A study of Mus musculus with 14 samples.

How the data were processed

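Polyadenylated RNA of mouse cortex was sequenced by the authors as stranded, paired-end libraries of 50 cycles, per the labels' protocols. The libraries of the miR29 mice (P40) were made with an RNeasy kit and TruSeq stranded mRNA reagents, and those of the Dnmt3a mice (4.5 months) with a Direct-zol kit and KAPA stranded mRNA reagents. The submitters' processing notes name cutadapt, STAR, Salmon and DESeq2, without versions or roles, and the builds hg19 and mm9 without saying for which step. Each model came as 1 deposited table of 24444 genes, and every column of per-sample values in both tables was used. The authors deposited the values on a log2 scale, made with the variance-stabilising transformation of DESeq2 over the libraries of each table, with size factors divided out. Each table was tested on its own, and no value was compared across tables except as a difference within each.

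The table of the Dnmt3a mice repeats its replicate names, so its columns map to groups but not to single mice. Its libraries are numbered here by column order only. In the same table the means of 2 sets of 4 libraries were equal for every gene within 5.5e-09, while the next smallest of the largest differences for other such sets was 0.791. An additive effect with 2 levels was therefore removed from the values before the table was deposited, which the processing notes do not mention. Set 1 holds Dnmt3a-WT libraries 1 and 2 and Dnmt3a-mi5 libraries 1 and 2, in which the Y-linked genes Kdm5d and Uty sat at 1 shared value each, as genes without reads do. Set 2 holds the other 4 libraries, in which they varied. Of the other Y-linked genes, Eif2s3y stood at 8.5222 in Dnmt3a-mi5 library 1 and at 8.4197 in the rest of set 1. Ddx3y varied in both sets. The removed effect may therefore be sex or a batch that goes with it, which these genes do not settle. Values of 2546 genes lay below the zero level of this table. Because the effect was removed, 1 residual degree of freedom too many is counted unless it enters the fit as a term, so counts are also given with the term. Sex could not be a further covariate in this table, because by Kdm5d and Uty it may coincide with the removed effect.

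The transformation was inverted in closed form from the zero level of each table (6.5861 and 7.6295 on the log2 scale). For the miR29 table this gave normalised counts and size factors of 0.773 to 1.20, and 85.6 to 90.0% of low values fell within 0.05 reads of a whole number. For the Dnmt3a table the recovered counts are approximate and the read depth is unknown. Transcript lengths, GC content, 3′ UTRs and coordinates came from GENCODE M21 (GRCm38), to which 23793 symbols matched directly, 290 through a synonym and 361 not at all. Libraries of a group correlated at 0.989 to 0.997, and the 10 most abundant genes took 3.38 to 5.14% of normalised counts.

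Groups were compared with limma 3.58.1 in R 4.3.3, using linear models, empirical Bayes with a mean-variance trend and Benjamini-Hochberg adjustment. Genes were tested when their mean lay at least 1 above the lowest value of the table on the log2 scale, which corresponds to about 48.0 and 80.1 normalised counts, and called at an adjusted p under 0.05. The 32 gene lists, with 710 entries, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, where at least 3 members were measured. The lists overlap in 18 pairs: autism-associated genes share 5 with excitatory synapse genes, 4 with voltage-gated channels, 2 with inhibitory synapse genes, 2 with other miR-29 targets and 2 with DNA methylation genes, and the other miR-29 targets share 6 with DNA methylation genes. Inhibitory synapse genes share 3 with interneuron markers, and the remaining 11 pairs share 1 gene each. Sites of miR-29 were exact matches of TGGTGCT, or TGGTGCTA for the longer match, in the longest annotated 3′ UTR. Genes over 100 kb counted as long. All 7-mers in at least 200 UTRs were ranked by the mean log2 difference of genes carrying them minus that of the other genes, after the trend with UTR length was removed. The same-sign overlap of calls was tested with Fisher's exact test, and the correlation across genes by enumerating the label assignments of both tables. Every Fisher's exact test here counts genes as independent replicates, which they are not, so its p values are too small where genes vary together. Values removed between the 2 sets make unbalanced assignments of the Dnmt3a libraries unequal to the real one, so assignments were also restricted to those with 2 libraries of each set per group. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for recovery, 7-mers and summaries.

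The comparisons, the settings above, the gene lists and the rule for named genes were fixed before the data were examined. The rule names the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, up to 4 members per list with the smallest p, and up to 12 genes called in both comparisons with the smallest rank sums. Dnmt3a, Dnmt3b, Dnmt1, Tet1, Tet2, Tet3, A330023F24Rik and the 4 Mir29 genes were always named. Several genes that the rule names are not reported here, though the counts over all genes and over lists include them. Alternatives were other filters, median centring, quantile normalisation, other variance priors, array weights, other thresholds, a replicate block, sex as a covariate, other site and length definitions and leaving out each library. Chosen after the data had been seen were the removed effect as a term, voom on the recovered reads, removal of GC and length trends, the shared calls without each library, the restriction to balanced assignments and a block for the header numbers within each set of the Dnmt3a libraries.

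In the miR29 table the deviations of libraries with the same replicate number correlated at 0.335, 0.204 and 0.186, and each library matched its own number best in the other group. The numbers may therefore pair the samples, but the labels give no pairing. With 3 libraries per group such a match can arise by chance, and by Y-linked genes number 3 joins a female miR29Nestin and a male miR29WT library. With the number as a block 3037 genes were called, 2286 of them also without it, and block values are printed beside a result only where the block changes its call. With voom on the recovered reads 2266 genes were called, 2232 of them also with the deposited values.

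The fits were tested on simulated data with the group sizes and spreads of each table. In the miR29 setting 29.9, 80.6 and 95.5% of genes changed by 0.25, 0.5 and 1 on the log2 scale were recovered, with 4.86% false calls. In the Dnmt3a setting the shares were 80.6, 97.0 and 100% with 6.57% false calls, and 77.6, 95.5 and 100% with 1.62% false calls when the removed effect was a term. Of 100 unchanged lists camera called 3 and 2 at an unadjusted p under 0.05. The genes were simulated independently and these lists drawn at random, so this does not test lists whose genes vary together. A shift of 0.1 planted in a set of genes was found as 0.0999 and 0.0994, and one planted in carriers of a 7-mer as 0.0983 and 0.0923, at rank 1. The correlation across genes was 0.00284 without and 0.641 with a shared effect, with permutation p values of 0.829 and 0.00286.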

Results

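Polyadenylated RNA from the cortex of 14 mice was sequenced in 2 mouse models of miR-29, a family of microRNAs that share 1 seed and lower the level of transcripts carrying the matching site TGGTGCT in their 3′ UTRs. In the first model both genomic clusters of the family were floxed and deleted with Nestin-Cre, a recombinase active in neural progenitors and the neurons and glia they give rise to. These miR29Nestin mice (n = 3) were compared with miR29WT mice (n = 3) at postnatal day 40. In the second model the family was intact and only 1 target was released from it: 5 miR-29 sites in the 3′ UTR of Dnmt3a, the enzyme that writes non-CG methylation in neurons, had been mutated by knock-in. These Dnmt3a-mi5 mice (n = 4) were compared with Dnmt3a-WT mice (n = 4) at 4.5 months. The first comparison asks which cortical transcripts differ without miR-29, and the second which of them differ when Dnmt3a alone escapes it. The 3 miR29Nestin libraries held 12.6, 11.8 and 13.05 M reads in genes and the 3 miR29WT libraries 10.9, 9.22 and 14.5 M, as recovered from the low values. Depth could not be recovered for the Dnmt3a-mi5 table, whose libraries had normalised totals of 10.2 to 10.4 M counts. Between 16667 and 17189 genes per library lay above the zero level in the first table and between 18002 and 18109 in the second.

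The microRNA genes themselves gave no check of the labels, because Mir29a, Mir29b-1, Mir29b-2 and Mir29c were listed at 0 in every library of every group, mutant and wild-type alike. In GENCODE M21 coordinates (GRCm38), Mir29a lies at 31062660 to 31062747 and Mir29b-1 at 31063023 to 31063093 on the minus strand of chromosome 6. Mir29b-2 lies at 195037040 to 195037120 and Mir29c at 195037547 to 195037634 on the plus strand of chromosome 1. The long non-coding transcript A330023F24Rik (chromosome 1, 194976375 to 195037904) runs over Mir29b-2 and Mir29c at its 3′ end. It stood at 8313, 10031 and 9992 normalised counts in the 3 miR29Nestin libraries and at 4119, 1230 and 1143 in the 3 miR29WT libraries, so miR29WT library 1 lay apart from its group. Its log2 difference was 2.26 (SE 0.34, limma adjusted p = 1.22e-03), and the call was lost when the variance prior was fitted robustly (adjusted p = 0.0627). In Dnmt3a-mi5 the same transcript did not pass (log2 difference −0.23, adjusted p = 0.186). Lncpint, a long intergenic RNA that starts upstream of Mir29b-1 on the same strand (chromosome 6, 31082565 to 31220488), rose from a group mean of 1.81 normalised counts in miR29WT to 431 in miR29Nestin, the largest rise of the named genes (adjusted p = 9.27e-08).

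Dnmt3a rose in both models, and more without miR-29 than with its own sites mutated. Its mean level was 5529 ± 300 normalised counts in miR29Nestin against 1662 ± 59.3 in miR29WT (SD, n = 3 each), a 3.33-fold difference. In Dnmt3a-mi5 it was 2080 ± 151 against 1145 ± 84.6 in Dnmt3a-WT (SD, n = 4 each), a 1.82-fold difference. Every mutant library lay above every wild-type library. The lowest and highest miR29Nestin libraries had 5275 and 5859 counts and the miR29WT libraries 1605 to 1724. The 4 Dnmt3a-mi5 libraries had 2249, 1958, 2163 and 1948 counts and the 4 Dnmt3a-WT libraries 1200, 1062, 1085 and 1234. On the deposited scale the log2 differences were 1.63 (SE 0.05, limma adjusted p = 8.18e-08) and 0.70 (SE 0.05, adjusted p = 6.24e-04), and the difference between them was 0.93 (SE 0.07), with ages, kits and normalisation also differing between the models. Exact permutation tests (2-sided) gave p = 0.1 for the first model, the smallest value that 20 assignments allow, and p = 0.0286 for the second, the smallest that 70 allow (p = 0.0556, the smallest for the 36 assignments balanced over the 2 sets of libraries between which an effect had been removed).

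**Figure D1:**
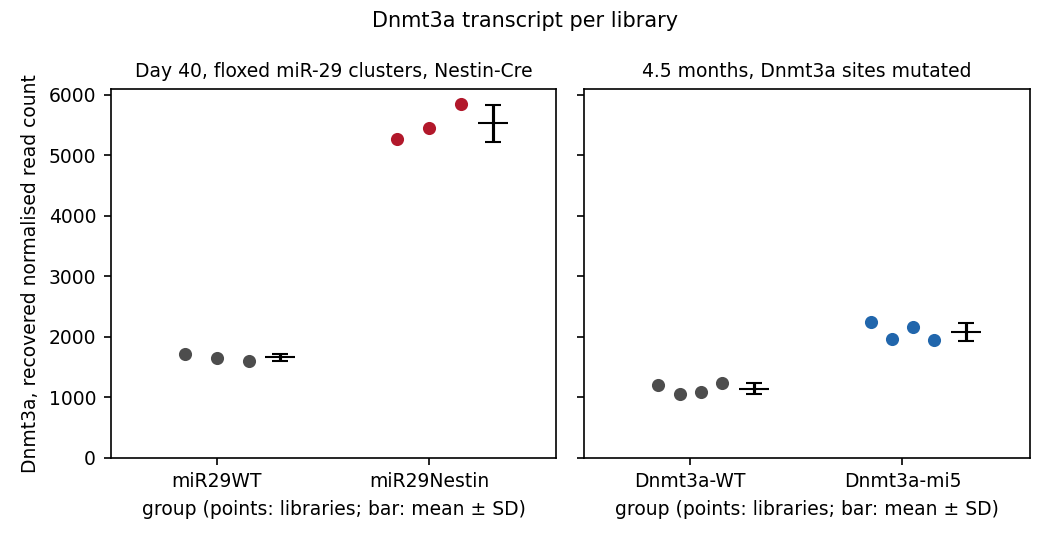
Normalised counts of Dnmt3a in each of the 14 libraries, with the group mean and SD, for miR29Nestin and miR29WT and for Dnmt3a-mi5 and Dnmt3a-WT. Every mutant library lies above every library of its own wild-type group, from 5275 against at most 1724 counts in the first model and from 1948 against at most 1234 in the second.

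The gene spans 3806007 to 3914443 on the plus strand of chromosome 12 (GRCm38, GENCODE M21), and its longest annotated 3′ UTR covers 3907745 to 3914443, or 6699 nucleotides. TGGTGCT occurs in it 5 times, at 3908572 to 3908578, 3908999 to 3909005, 3910835 to 3910841, 3911405 to 3911411 and 3911474 to 3911480. Counted from the first base of the UTR, these sites begin at positions 828, 1255, 3091, 3661 and 3730. The sites at 3661 and 3730 are followed by an A and so form the longer match TGGTGCTA. From the first to the last base of the 5 sites the span is 2909 bp, the length that the labels' protocols give for the replaced region, in which each site was changed to CACGGCT.

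**Figure D2:**
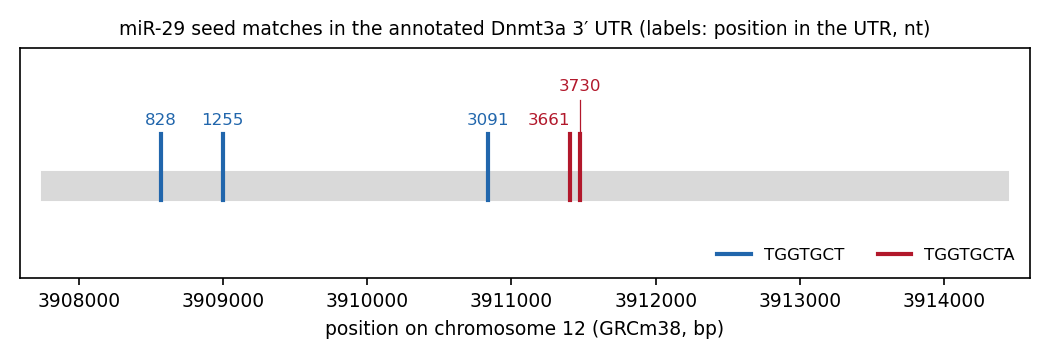
The annotated 3′ UTR of Dnmt3a drawn to scale in GRCm38 coordinates on chromosome 12, with the 5 TGGTGCT sites marked. The sites lie between 3908572 and 3911480, at positions 828 to 3730 of the 6699 nucleotides.

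Without miR-29, 1084 genes were higher and 1205 lower in the P40 cortex, 19.1% of the 12014 tested, and the changes were mostly small, with a median absolute log2 difference of 0.29 among the called genes. Besides Dnmt3a, the genes with the largest rises included several with miR-29 sites and metabolic enzymes. Rtp1, Krt12, Aldh1a1, Plin4 and Cd6, also among the largest rises, had a count of 0 sites. Col26a1, a collagen with 4 sites, reached 852 ± 59.8 normalised counts against 209 ± 30.9 (SD, n = 3 each; 4.09-fold). Bdh1, a mitochondrial ketone-body dehydrogenase with 4 sites, reached 2207 ± 89.2 against 816 ± 64.4 (2.71-fold). Among the largest falls were Adcy1, the calcium-stimulated adenylyl cyclase of neurons, at 6215 ± 394 against 15180 ± 950, and Serpina3n, a protease inhibitor of reactive astrocytes, at 221 ± 23.9 against 736 ± 31.5.

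Adamts17, a secreted metalloprotease with 3 sites, had a log2 difference of 1.48, Tmem229b one of 1.45 (2134 ± 103 against 668 ± 17.5 normalised counts) and Aldh1a1, a retinaldehyde dehydrogenase, one of 1.41 (1428 ± 85.7 against 436 ± 88.6). Rtp1, which helps odorant receptors to the cell surface, rose from 8.14 ± 5.78 to 250 ± 55.7 normalised counts, and Krt12, a keratin of the corneal epithelium, from 56.8 to 388. Ccdc28b rose by 1.28 on the log2 scale, the lipid-droplet protein Plin4 by 1.16 and the lymphocyte receptor Cd6 by 1.15. The Plin4 call was lost with a robust variance prior (adjusted p = 0.0570). Zbtb18, a transcriptional repressor needed for cortical neuron development, had a log2 difference of −0.87 (1662 ± 116 against 3200 ± 222 counts), and Cacna1g, a T-type calcium channel, one of −0.85 (724 ± 15.9 against 1452 ± 83.4). Nrep had a log2 difference of −0.97, Ramp3, a partner protein of calcitonin-type receptors, one of −0.91 and the axon guidance receptor Robo3 one of −0.88. The differences of Sertm1, Lypd1 and the receptor phosphatase Ptprk were −0.86, −0.85 and −0.81. Tnnc1, troponin C of slow muscle, stood at 14.5 ± 5.70 counts against 143 ± 29.1. Tuba1c, an alpha-tubulin, had the most negative value, −1.46, with a wide spread in miR29Nestin (64.0 ± 98.9 against 318 ± 101 counts; adjusted p = 9.19e-03). Its call was lost without miR29WT library 2 (adjusted p = 0.0503) and with a robust variance prior (adjusted p = 0.131). For the other genes of this paragraph limma gave adjusted p values of at most 3.15e-03, that of Plin4.

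By the directional fry test 13 of the 28 lists passed, 11 of them among the 14 that passed camera. In other splits of the same libraries, which mix the groups, 5 to 12 lists passed camera with the preset correlation. Its p values for lists therefore overstate how firmly a list differs between the groups. The tested genes included 3962 at an unadjusted p under 0.05. Groups did not overlap for 2232 higher and 2251 lower genes, 37.3% of those tested against the 10% that chance gives for 3 against 3. Only 22 rises and 4 falls exceeded 1 on the log2 scale, which understates the fold of low genes because the variance stabilisation compresses them. The count of called genes was 1474 without miR29Nestin library 2, 1399 without miR29WT library 2 and 1435 without miR29WT library 3. The mice of the 2 groups differed in their mix of sexes by Y-linked genes, with 1 male of 3 in miR29Nestin and 2 of 3 in miR29WT.

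Tet3, Tet1 and Tdg, which act in the removal of DNA methylation, rose beside Dnmt3a without miR-29, and known targets of the family rose as a group. Tet3, which oxidises 5-methylcytosine and has 8 sites in its 3′ UTR, reached 2209 ± 154 normalised counts against 1088 ± 81.5 (SD, n = 3 each; 2.03-fold; limma adjusted p = 1.07e-05). Tet1, with 7 sites, had a log2 difference of 0.46 (263 ± 49.6 against 151 ± 13.8 counts) and Tdg, the glycosylase that acts after TET enzymes and has 3 sites, one of 0.34. Tet2 (−0.04, adjusted p = 0.808) and the maintenance methyltransferase Dnmt1 (0.01, adjusted p = 0.917) did not pass. Dnmt3b lay below the filter at means of 20.2 and 12.3 counts. In the list of DNA methylation writers, erasers and readers, 4 of 17 measured genes rose and 1 fell, over all genes and adjusted over the list alone, and the list did not pass (median 0.02, camera adjusted p = 0.0685, 0.0259 without miR29Nestin library 1 and 0.0434 with GC and length trends removed and the replicate number as a block).

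Of the other miR-29 targets, 15 of 30 rose and 3 fell (16 and 4 adjusted over the list alone), with a median of 0.25 and a camera adjusted p = 2.41e-06. With an estimated correlation the adjusted p = 0.171. Examples besides Dnmt3a and Tet3 were Hrk, a pro-apoptotic BH3-only protein with 3 sites (0.78), and the histone demethylase Kdm5b (0.46). Among the collagens and matrix proteins known as targets, 9 of 15 rose and 1 fell, the same numbers adjusted over the list alone (median 0.28, camera adjusted p = 1.12e-03). The adjusted p = 0.276 with an estimated correlation. Eln, the elastin gene, with 3 sites, had a log2 difference of 0.65, the basement membrane genes Col4a2 and Lamc1 differences of 0.47 and 0.39, and Col19a1 one of 0.54. For Col19a1 0 sites were counted. In the apoptosis and p53 list 4 of 17 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.08, camera adjusted p = 0.0190, and adjusted p = 0.390 with an estimated correlation). The 4 were the cell-death effectors Bak1 (0.50) and Bax (0.28), the cell-cycle inhibitor Cdkn1a (0.59) and the survival protein Bcl2l2 (0.25).

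Neuronal gene groups were lower without miR-29 by camera with the preset correlation, a test that also passed 5 to 12 lists in other splits of these libraries. Of 46 excitatory synapse genes 18 fell and 2 rose (24 and 3 adjusted over the list alone; median −0.18, camera adjusted p = 2.48e-05). With an estimated correlation the adjusted p = 0.183. The postsynaptic scaffolds Shank3 (−0.49) and Dlg4 (−0.33) and the kainate receptor subunit Grik3 (−0.29) were among them. Of 22 inhibitory synapse genes 9 fell and 1 rose (11 and 2 adjusted over the list alone; median −0.15, camera adjusted p = 1.92e-03, and adjusted p = 0.435 with an estimated correlation). The GABA receptor subunits Gabra3, Gabra5 and Gabbr2 had log2 differences of −0.64, −0.61 and −0.45, and Gad2, which makes GABA, one of −0.52. Of 50 autism-associated genes 20 fell and 1 rose (24 and 2 adjusted over the list alone; median −0.18, camera adjusted p = 4.31e-06, and adjusted p = 0.435 with an estimated correlation), with Reln, a secreted protein that guides cortical layering, at −0.72. This list holds 5 of the excitatory synapse genes. Of 19 markers of excitatory neurons and cortical layers 8 fell and 2 rose (10 and 2 adjusted over the list alone; median −0.26, camera adjusted p = 1.92e-03, and adjusted p = 0.171 with an estimated correlation). They included Otof (−0.68) and the vesicular glutamate transporter Slc17a7 (−0.27).

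Genes of immature neurons and progenitors also fell, 12 of 25, while 1 rose (16 and 3 adjusted over the list alone; median −0.20, camera adjusted p = 1.43e-04). With an estimated correlation the adjusted p = 0.183, and with the stricter filter on low values 0.0675. Marcksl1 (−0.77), the tubulin Tubb2b (−0.65), the adhesion protein Igsf9 (−0.63) and the transcription factor Sox4 (−0.39) led the list. Of 29 immediate early genes, which neuronal activity induces, 5 fell and 1 rose, the same numbers adjusted over the list alone. The list's median was −0.12, its camera adjusted p = 0.0472, and the adjusted p = 0.572 with an estimated correlation. Egr3 had a difference of −0.59. Removing miR29Nestin library 3 (adjusted p = 0.0975), miR29WT library 1 (0.275) or miR29WT library 2 (0.218), or applying the stricter filter (0.0675), ended the call of this list.

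Metabolic lists went both ways, while the glial and leptomeningeal lists that passed were higher. Of 19 cholesterol synthesis genes 10 passed, all of them lower (12 adjusted over the list alone; median −0.26, camera adjusted p = 8.33e-06, and adjusted p = 0.171 with an estimated correlation). Srebf2, the transcriptional regulator of the pathway, had a difference of −0.37, Nsdhl −0.38 and Fdft1, which makes squalene, −0.32. Of 46 nuclear genes of mitochondrial oxidative phosphorylation 12 were higher (16 adjusted over the list alone, and 25 at an unadjusted p under 0.05, all higher; median 0.13, camera adjusted p = 2.41e-06, and adjusted p = 0.390 with an estimated correlation). The complex III gene Uqcrc1 (0.24) was called, and the call was lost without miR29WT library 2 (adjusted p = 0.0701). Of 15 astrocyte markers 5 rose and 1 fell (5 and 2 adjusted over the list alone; median 0.13, camera adjusted p = 1.92e-03, and adjusted p = 0.171 with an estimated correlation), with the connexins Gjb6 (0.64) and Gja1 (0.38), the filament protein Gfap (0.54) and Ntsr2 (0.40). Of 9 oligodendrocyte precursor markers 2 rose, also adjusted over the list alone (median 0.17, camera adjusted p = 0.0158, and adjusted p = 0.192 with an estimated correlation), with Pdgfra at 0.30. That list was lost with the stricter filter (adjusted p = 0.0508). Of 12 leptomeningeal fibroblast markers 5 rose, also adjusted over the list alone (median 0.17, camera adjusted p = 1.92e-03, and adjusted p = 0.435 with an estimated correlation), with the growth factor Igf2 at 0.84, Cemip at 0.48, Islr at 0.47 and Mgp at 0.45.

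Several cell type lists did not pass although single members did. Pvalb, the calcium buffer of fast-spiking interneurons, rose to 1411 ± 71.8 from 748 ± 73.0 normalised counts (SD, n = 3 each; limma adjusted p = 4.29e-05), whereas Calb2, of another interneuron class, had a difference of −0.44. The interneuron list had 3 higher and 5 lower of 20 (4 and 6 adjusted over the list alone; median −0.07, camera adjusted p = 0.311). Of 43 voltage-gated channels 7 rose and 11 fell (8 and 11 adjusted over the list alone; median −0.08, camera adjusted p = 0.134, and 0.0483 without miR29Nestin library 3), and the potassium channel Kcna1 (0.51) rose. Of 13 perineuronal net genes 3 rose and 1 fell (4 and 2 adjusted over the list alone; median 0.08, camera adjusted p = 0.271), with the proteoglycan Bcan at 0.45 and the link protein Hapln1 at 0.39. Of 9 reactive glia genes 4 rose and 1, Serpina3n, fell, also adjusted over the list alone (median 0.25, camera adjusted p = 0.154), with Apoe, the main lipid carrier of the brain, at 0.41. Of 10 interferon and MHC genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.13), with Ifi27 at 0.55 and H2-D1 at 0.34. That list had a camera adjusted p = 0.0670, which was 0.0427 without miR29Nestin library 1, 0.0269 without miR29Nestin library 3 and 0.00663 with the stricter filter.

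Among oligodendrocyte and myelin genes 4 of 20 rose, also adjusted over the list alone, with Mobp at 0.33 (median 0.08, camera adjusted p = 0.0710). This list passed with the replicate number as a block (adjusted p = 0.0489), without miR29Nestin library 3 (0.00330) and without miR29WT library 1 (0.00627). No striatum marker of 10 passed with limma, and none had an unadjusted p under 0.05 (median −0.15, camera adjusted p = 0.375). With the block the striatum list passed (adjusted p = 0.0472), as did its members Penk (−0.55, adjusted p = 2.25e-04), Syndig1l (−0.41, 0.00545) and Adora2a (−0.28, 0.0174). Penk passed as well with sex as a covariate (0.0329) and without miR29Nestin library 3 (0.0352), and the list also passed without miR29Nestin library 3 (0.00782) or miR29WT library 1 (0.0415). Endothelial markers (14 measured, 2 higher, also adjusted over the list alone, median 0.02, camera adjusted p = 0.478) included Vwf at 0.46 and Ly6a at 0.40, and Ly6c1 (0.30) passed with the block (adjusted p = 0.0118), with array weights (0.0147) and without miR29Nestin library 3 (0.0496). Mural cell markers (9 measured, 2 higher and 1 lower, also adjusted over the list alone) had a median of 0.17 and a camera adjusted p = 0.266, with Rgs5, a pericyte marker, at −0.35. For 17 microglia markers the median was −0.02 and the mean 0.00126, and neither a member by limma, with 1 at an unadjusted p under 0.05, nor the list passed (camera adjusted p = 0.938). Of 51 ribosomal protein genes 1 was called lower by limma over all genes, 0 adjusted over the list alone and 5 at an unadjusted p under 0.05 (median −0.03, camera adjusted p = 0.311, 0.0427 without miR29Nestin library 1 and 0.00585 with GC and length trends removed and the block), and Rpl10 (−0.16) passed with the block (adjusted p = 0.0415), with array weights (0.0213) and without miR29WT library 1 (0.0409). Of 5 hippocampal markers Prox1 was called lower at −0.21 (adjusted p = 0.0444), a call lost without any 1 of the 6 libraries (adjusted p up to 0.129), and 1 higher and 2 lower passed adjusted over the list alone (list median −0.12, camera adjusted p = 0.626). The 4 thalamic markers, 1 of them at an unadjusted p under 0.05, had a median of 0.05 (camera adjusted p = 0.478). The mitochondrially encoded, choroid plexus, olfactory bulb and blood lists had fewer than 3 measured members and were not tested.

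**Figure D3:**
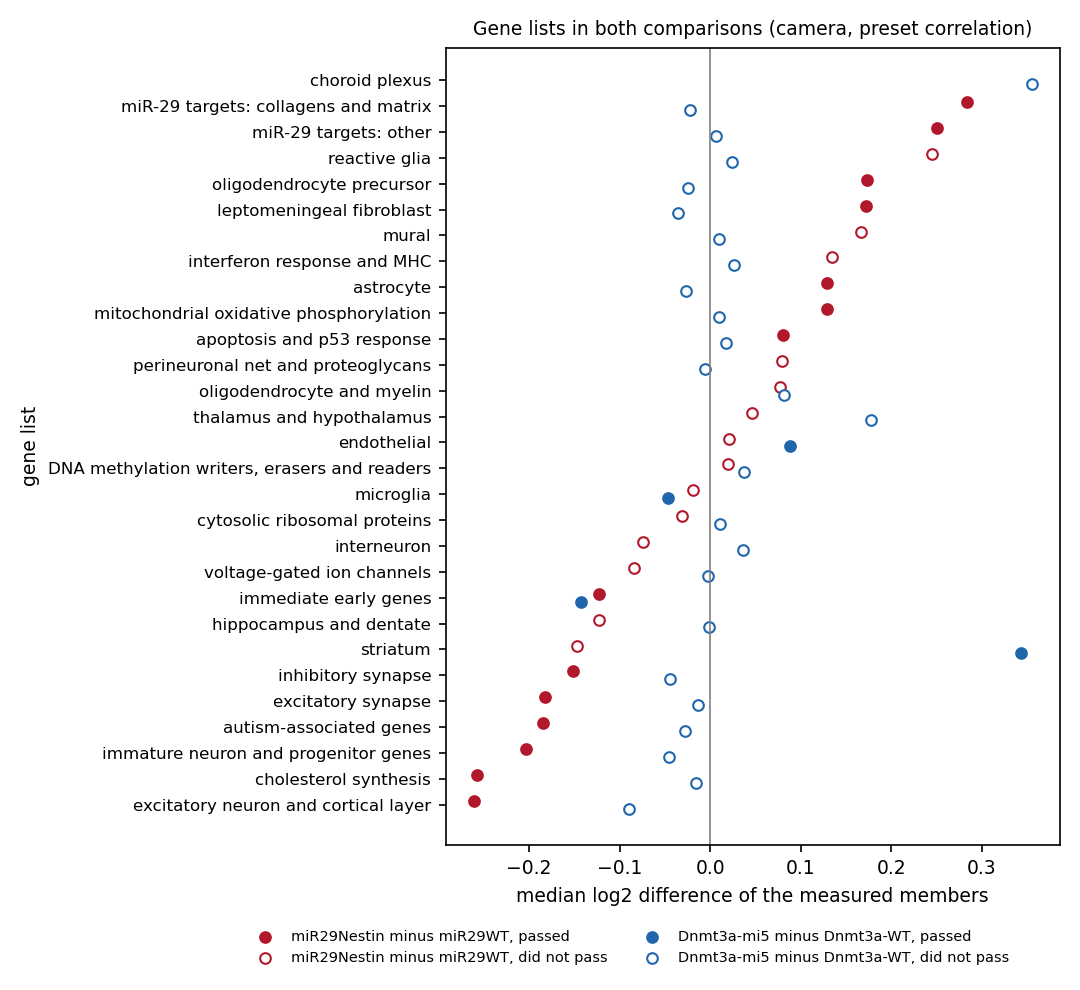
Median log2 difference of each gene list in miR29Nestin against miR29WT and in Dnmt3a-mi5 against Dnmt3a-WT, with filled points for lists that passed camera with the preset correlation and open points for the others. In miR29Nestin 14 of 28 lists passed, among them excitatory synapse genes at −0.18 and other miR-29 targets at 0.25, and in Dnmt3a-mi5 4 of 29, among them immediate early genes at −0.14.

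Transcripts with miR-29 sites were higher without miR-29, and more so the more sites they had. The median log2 difference was −0.01 for 9774 genes with no TGGTGCT in the longest annotated 3′ UTR, 0.02 for 1626 genes with 1 site, 0.05 for 253 with 2 and 0.13 for 65 with 3 or more. The median of the 1944 genes with at least 1 site lay 0.0419 above that of genes with none (camera p = 0.00575, and p = 0.0775 with an estimated correlation). Without miR29Nestin library 3 the shift was 0.0253, with a camera p of 0.0420. The 422 genes with the longer match TGGTGCTA lay 0.11 above (camera p = 2.77e-09, and p = 0.0132 with an estimated correlation). Of the genes with a site 17.3% were called higher against 7.38% of those without (odds ratio 2.62, Fisher's exact p = 9.85e-38), and for the longer match the share was 28.4%. The Fisher p counts genes as independent replicates, which they are not. All 14133 7-mers found in at least 200 UTRs were ranked after the trend with UTR length was removed. By the mean log2 difference of genes carrying a 7-mer minus that of the other genes, TGGTGCT ranked 2 (0.0775). GGTGCTA, which overlaps it by 6 bases, ranked 1 (0.109).

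**Figure D4:**
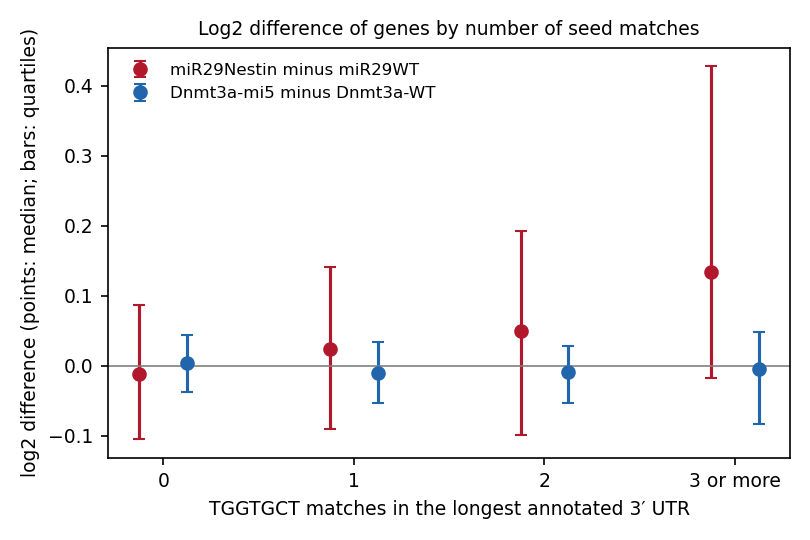
Median log2 difference of genes grouped by the number of TGGTGCT sites in the 3′ UTR, with lower and upper quartiles, in both comparisons. In miR29Nestin the median runs from −0.01 with no site to 0.13 with 3 or more, and in Dnmt3a-mi5 all 4 medians lie within 0.01 of 0.

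Long genes were lower without miR-29. The median of 1967 genes over 100 kb differed from that of 10000 shorter genes by −0.0793 (camera p = 3.83e-05, and p = 0.262 with an estimated correlation). The shift was −0.0529 without miR29Nestin library 1. Of the long genes 19.7% were called lower against 8.15% of shorter ones (odds ratio 2.76, Fisher's exact p = 1.72e-46). The Fisher p counts genes as independent replicates, which they are not. A split of the same libraries that mixed the groups also gave a long gene shift of −0.0701. Log2 differences went with transcript GC content across genes (r = 0.130), and after GC and length trends were removed the shift was −0.0381.

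Far fewer genes differed in Dnmt3a-mi5 at 4.5 months: 24 were higher and 61 lower, 0.797% of the 10670 tested. That fit counts 1 residual degree of freedom too many, and with the removed effect as a term 3 were higher and 10 lower. Dnmt3a itself led the rises, and activity-induced genes led the falls. Btg2, an anti-proliferative immediate early gene, stood at 151 ± 17.6 normalised counts against 298 ± 27.4 (SD, n = 4 each), Cyr61, a secreted matrix protein, at 69.6 ± 12.9 against 149.8 ± 9.47 and Fos, a subunit of the AP-1 transcription factor, at 341 ± 27.9 against 541 ± 55.7. Met, the receptor of hepatocyte growth factor, stood at 55.6 ± 2.61 against 121 ± 19.1, and Scrt2, a neuronal zinc-finger repressor, rose to 394 ± 41.9 from 244 ± 19.1. The counts are approximate here because the deposited values had been adjusted after normalisation.

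On the log2 scale the limma differences were −0.45 for Btg2 (adjusted p = 0.00386), −0.39 for Fos (0.0105), −0.38 for Cyr61 (0.00652), −0.34 for Met (0.00919) and 0.36 for Scrt2 (0.0105). The MAP kinase phosphatases Dusp1 and Dusp6, both induced by activity, had differences of −0.35 and −0.34, Cacna2d1, a calcium channel subunit that binds gabapentin, −0.32 and Cpeb4, a regulator of mRNA translation, −0.32. Mef2c, a transcription factor of excitatory neurons, had −0.40, Luzp2 −0.36, the netrin receptor Unc5d −0.31 and Pgm2l1 −0.30. Among the rises were Tsc22d3, a glucocorticoid-induced gene (0.32), Jade2 (0.28), the VEGF receptor Flt1 (0.25), the linker histone Hist1h1c (0.22), Baiap2 (0.21), Dpf1 (0.20), the histone demethylase Kdm6b (0.20), Ankrd13a (0.20), Chchd10 (0.19) and Acin1 (0.19). Tet3 (0.09, adjusted p = 0.217), Dnmt1 (0.05, 0.394), Tet2 (0.03, 0.844) and Tet1 (−0.0043, 0.972) did not pass, and Dnmt3b lay below the filter at 5.92 and 5.80 counts.

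No called gene of this comparison exceeded 1 on the log2 scale, which understates the fold of low genes here too because the variance stabilisation compresses them. There were 2025 genes at an unadjusted p under 0.05, and groups did not overlap for 569 higher and 712 lower genes, 12.0% of those tested against the 2.86% that chance gives for 4 against 4. The 2.86% treats all assignments of the libraries as equal, which they are not in this table. The deposited values had a per-gene difference between 2 sets of 4 libraries removed. By the Y-linked genes Kdm5d and Uty these sets may coincide with sex, while Ddx3y varied in both. With that effect as a term the count of called genes was 13: Dnmt3a, Jade2 and Scrt2 higher, and Btg2, Cyr61, Met, Fos, Cpeb4, Cx3cr1, Dusp6, Cacna2d1, Tmem65 and Ptprk lower, with Dnmt3a at adjusted p = 1.53e-03 and Cacna2d1 and Ptprk at 0.0420. Tmem65 and Ptprk are named for this count, after their values were seen. Within set 1 Dnmt3a was higher by 0.73 and within set 2 by 0.67. The count rested on single libraries: it was 13 without Dnmt3a-WT library 1, 12 without 3, 8 without 4 and 175 without 2, and 12, 14, 21 and 11 without Dnmt3a-mi5 libraries 1, 2, 3 and 4. Dnmt3a, Scrt2, Jade2, Btg2, Cyr61, Met and Cpeb4 kept their calls in each such fit that tested them (highest adjusted p 0.0488, for Scrt2). Fos lost its call without Dnmt3a-WT library 4 (adjusted p = 0.0587), Cacna2d1 without Dnmt3a-WT library 4 (0.0587) or Dnmt3a-mi5 library 4 (0.0512), and Dusp6 without Dnmt3a-WT libraries 3 (0.0605) or 4 (0.0587) or Dnmt3a-mi5 libraries 1 (0.0616) or 4 (0.0512). The other 14 genes of the 24 named lost theirs in most of these fits, though never without Dnmt3a-WT library 2, with highest adjusted p values of 0.0815 for Hist1h1c to 0.134 for Tsc22d3. None of these 14 was called with the removed effect as a term (adjusted p from 0.0785 for Dusp1), and of them only Dusp1 without the filter on low values, where 25 genes were called.

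Immediate early genes fell as a group in Dnmt3a-mi5. Of 28 measured, 5 passed, all of them lower (10 lower and 1 higher adjusted over the list alone), with a median of −0.14 (camera adjusted p = 1.33e-06, and adjusted p = 0.524 with an estimated correlation). The 5 were Btg2, Fos, Cyr61, Dusp1 and Dusp6. Microglia markers fell too, with 2 of 15 lower (5 adjusted over the list alone; median −0.05, camera adjusted p = 3.06e-03, and adjusted p = 0.524 with an estimated correlation). The fractalkine receptor Cx3cr1 stood at 487 ± 12.0 normalised counts against 629 ± 22.2 (−0.24, limma adjusted p = 0.00919), a call kept without each library in turn. The purinergic receptor P2ry12 had a difference of −0.30 (adjusted p = 0.0495, and 0.114 with the removed effect as a term), a call lost without every library other than Dnmt3a-WT library 2 (up to 0.121). Of 11 endothelial markers 1, Flt1, rose (3 adjusted over the list alone; median 0.09, camera adjusted p = 3.06e-03, and adjusted p = 0.524 with an estimated correlation). Striatum markers were higher as a list (median 0.34, camera adjusted p = 2.38e-03, and adjusted p = 0.644 with an estimated correlation), although none of the 10 members passed with limma, over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. The phosphodiesterase Pde10a (0.50), Ppp1r1b (0.47) and the dopamine receptors Drd1 and Drd2 (both 0.35) had the values typical of it.

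These 4 lists passed with the removed effect as a term as well. With the stricter filter the camera adjusted p was 0.0558 for immediate early genes, 0.190 for microglia and 0.0995 for striatum markers, and the endothelial list had fewer than 3 members left. By fry 0 lists passed, with 7 at an unadjusted p under 0.05. As many lists passed in other splits of the same 8 libraries. The mean of the striatum markers was 10.62 and 10.64 in Dnmt3a-mi5 libraries 1 and 3, 10.05 and 9.87 in libraries 2 and 4, and 9.91, 9.89, 9.73 and 10.23 in Dnmt3a-WT libraries 1 to 4. With this mean as a covariate 28 genes were called, the immediate early genes had a median of −0.20 and Dnmt3a a difference of 0.62.

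The other lists did not pass in Dnmt3a-mi5. For each, brackets give in this order the genes higher and lower adjusted over the list alone, the median log2 difference and the camera adjusted p. Dnmt3a was the only gene called by limma over all genes among 25 other miR-29 targets (1 and 2, 0.00698, 0.964) and 16 genes of the DNA methylation list (1 and 1, 0.04, 0.166). Over all genes limma made 1 call among 46 excitatory synapse genes (0 and 3, −0.01, 0.490) and 2 among 50 autism-associated genes (2 and 3, −0.03, 0.166), of which Kdm6b was higher. Kcnip3, a potassium channel partner, was the only call, at 0.16, among 44 voltage-gated channels (4 and 0, −0.00243 with a mean of 0.02, 0.666). Slc1a2, the astrocytic glutamate transporter, was the only call among 15 astrocyte markers (1 and 1, −0.03, 0.227), at −0.25 (adjusted p = 0.0478, and 0.426 after quantile normalisation), and Nrn1 among 5 hippocampal markers (0 and 1, −0.000648, 0.24), at −0.23. Kcnip3, Slc1a2 and Nrn1 lost their calls without every library other than Dnmt3a-WT library 2, with adjusted p up to 0.134, 0.132 and 0.103.

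No gene was called by limma over all genes in the remaining lists, for which brackets add at the end the number at an unadjusted p under 0.05. These were 12 collagen and matrix genes (1 and 1, −0.02, 0.964, 3 genes), 16 apoptosis genes (0 and 0, 0.02, 0.609, 2 genes), 22 inhibitory synapse genes (1 and 3, −0.04, 0.166, 6 genes), 20 immature neuron genes (0 and 1, −0.05, 0.206, 4 genes) and 19 excitatory neuron and layer markers (0 and 1, −0.09, 0.166, 4 genes). Others were 10 perineuronal net genes (1 and 2, −0.01, 0.416, 4 genes), 8 interferon genes (0 and 0, 0.03, 0.560, 2 genes), 8 reactive glia genes (0 and 0, 0.02, 0.461, 0 genes), 19 cholesterol synthesis genes (0 and 0, −0.02, 0.206, 3 genes), 46 oxidative phosphorylation genes (0 and 0, 0.00992, 0.227, 6 genes) and 51 ribosomal protein genes (0 and 0, 0.01, 0.411, 3 genes). Among cell types they were 15 interneuron markers (0 and 0, 0.04, 0.227, 4 genes), 6 oligodendrocyte precursor markers (0 and 2, −0.02, 0.304, 2 genes), 5 mural markers (2 and 0, 0.00972, 0.206, 2 genes), 12 leptomeningeal markers (0 and 0, −0.03, 0.548, 0 genes) and 3 thalamic markers (0 and 0, 0.18, 0.360, 0 genes). The 20 oligodendrocyte genes (0 and 0, 0.08, 0.206, 1 gene) had an adjusted p of 0.00508 without Dnmt3a-WT library 1, 0.00783 without Dnmt3a-WT library 3 and 0.0403 without Dnmt3a-mi5 library 4. The cholesterol synthesis list had 0.0424 with GC and length trends removed and the removed effect as a term. The 5 choroid plexus markers (0 and 0, 0.36, 0.227, 0 genes) had 0.0430 without Dnmt3a-WT library 3 and 0.00991 without Dnmt3a-mi5 library 3. The mitochondrially encoded, olfactory bulb and blood lists had fewer than 3 measured members.

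Transcripts with miR-29 sites were not higher in Dnmt3a-mi5, where the family is intact. The median of the 1778 genes with TGGTGCT differed from that of genes without it by −0.0131 (camera p = 0.0853, and p = 0.0438 with an estimated correlation), and by −0.0165 without Dnmt3a-mi5 library 1 (p = 0.0284). Of the genes with TGGTGCT 1.01% were called lower against 0.471% of genes without it (odds ratio 2.16, Fisher's exact p = 0.00862). Neither these shifts nor the Fisher test allow for UTR length. After the trend with UTR length was removed, the mean of genes with TGGTGCT lay 0.00085 above that of the others, rank 5923 among 13855 7-mers, so no lowering remained. Long genes were lower here as well: the median of the 1852 genes over 100 kb differed from that of shorter ones by −0.0273 (camera p = 1.88e-04, and p = 0.0222 with an estimated correlation), and 1.08% of them were called lower against 0.467% of shorter genes (odds ratio 2.33, Fisher's exact p = 0.00337). Log2 differences went with transcript GC content across genes (r = 0.413), and after GC and length trends were removed the shift was −0.0107.

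Few genes were called in both models, and how many depended on single Dnmt3a libraries. Of 10610 genes tested in both, 18 were called lower in each, where independent lists would share 6.57 (Fisher's exact p = 4.61e-05), and 5 higher in each, where they would share 2.09 (p = 0.0517). These p values count genes as independent, which they are not, and the calls come from the fit without the removed effect as a term. Besides Dnmt3a the shared rises were Tsc22d3 (1.03 in miR29Nestin and 0.32 in Dnmt3a-mi5), Scrt2, Ankrd13a and Ina, the last of which is named for this count after its values were seen. Shared falls included Mef2c (−0.72 and −0.40), Ptprk (−0.81 and −0.30), Cacna2d1 (−0.63 and −0.32), Pgm2l1 (−0.60 and −0.30), Klhl23 (−0.61 and −0.18), Adam19 (−0.58 and −0.19), B4galt2 (−0.49 and −0.15), Gng2, a G protein subunit (−0.47 and −0.26), and Unc5d (−0.41 and −0.31). Apc, a brake on Wnt signalling (0.61 and −0.27), and Slc1a2 (0.16 and −0.25) went opposite ways. The numbers shared higher and lower were 2 and 2 without Dnmt3a-WT library 1, 15 and 43 without 2, 2 and 2 without 3 and 2 and 0 without 4. They were 2 and 1 without Dnmt3a-mi5 library 1, 2 or 4 and 2 and 3 without library 3, and 18 to 29 genes in all were shared without single miR29 libraries. In Dnmt3a-mi5, Adam19 lost its call without each of the 8 libraries (adjusted p up to 0.134) and Ptprk without 5 of them, Dnmt3a-WT libraries 3 and 4 and Dnmt3a-mi5 libraries 1, 2 and 3 (up to 0.0776). Gng2 (up to 0.0984), B4galt2 (up to 0.127), Klhl23 (up to 0.134) and Apc (up to 0.134) lost theirs in most of these fits, though not without Dnmt3a-WT library 2. With the removed effect as a term, 2 genes were shared higher and 2 lower, against 0.272 and 0.985 for independent lists (Fisher's exact p = 0.0232 and 0.258). The 2 higher were Scrt2 and Dnmt3a, the gene whose sites were mutated, and the overlap was not tested without Dnmt3a. Across the 10610 genes, which are not independent replicates, the log2 differences correlated at r = 0.279 (Spearman 0.266), with an exact permutation p = 0.00571 and 0.0143 over 350 combinations of group labels (p = 0.0111 and 0.0167 over the 180 that are balanced over the 2 sets). Another combination of labels reached an absolute r of 0.281. In both models the log2 differences went with transcript GC content (r = 0.130 and 0.413). After GC and length trends were removed the correlation was 0.241 (permutation p = 0.0257, and 0.0278 over the balanced combinations), and another combination reached 0.297. The sign was shared by 58.8% of genes and by 66.7% of the 2124 called in miR29Nestin. The models share no wild-type libraries.

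**Figure D5:**
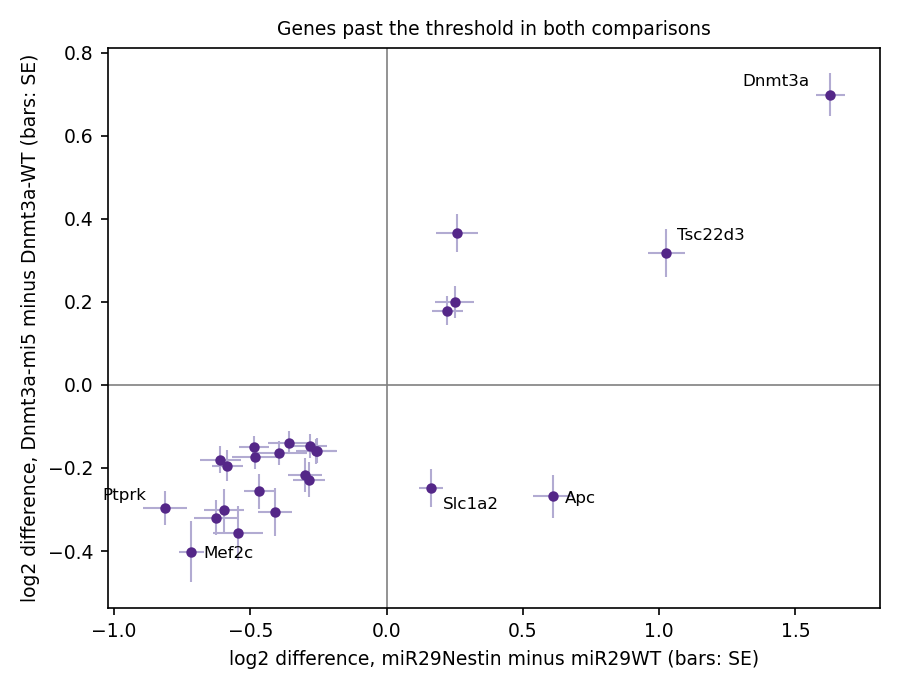
Log2 differences in miR29Nestin against miR29WT (horizontal) and Dnmt3a-mi5 against Dnmt3a-WT (vertical) for the 25 genes called in both, with bars of 1 SE. Of these genes 18 lie in the quadrant lower in both, 5, led by Dnmt3a, in the quadrant higher in both, and Apc and Slc1a2 in opposite quadrants. The calls are from the fit without the removed effect as a term, with which 2 genes were shared higher and 2 lower.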

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

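The tests with GC and length trends removed, of immediate early genes against the level of Dnmt3a and of a wrong label for miR29WT library 1 were chosen only after the results were seen.

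Among groups of 4 libraries, a single library stood apart from the other 3 by most of the group's range for 12 of 278 combinations of a named gene and a group, where chance gives 13.9. Of the 12, 10 are given here and 2 are not reported. In Dnmt3a-WT the gap was 0.838 of the range for Luzp2 (library 3, 11.30 against 11.38 to 11.39 on the log2 scale) and 0.8445 for A330023F24Rik (library 3, 9.91 against 9.68 to 9.72). It was 0.9216 for Hcn2 (library 2, 11.16 against 11.42 to 11.45), 0.9421 for Slc2a1 (library 1, 9.77 against 9.94 to 9.95) and 0.8908 for Rgs5 (library 2, 9.94 against 9.91). In Dnmt3a-mi5 it was 0.899 for Adarb2 (library 1, 9.06 against 8.92 to 8.94) and 0.909 for Siglech (library 1, 8.55 against 8.63 to 8.64). It was 0.8345 for Lhx6 (library 3, 9.27 against 9.19 to 9.20), 0.8366 for Ntsr2 (library 3, 10.33 against 10.40 to 10.41) and 0.9117 for Slc1a2 (library 4, 15.30 against 15.37 to 15.38). Of the genes given Luzp2 and Slc1a2 were called.

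Immediate early genes were lower in Dnmt3a-mi5. Their median stayed at −0.152 (SE over libraries 0.053) after removal of the GC and length trend and was −0.199 (SE 0.074) with the striatum marker mean as a covariate, which argues against each of these as the whole cause, while medians of −0.163 in set 1 of the libraries and −0.186 in set 2 (larger SE 0.140, 2 libraries per group) leave open an origin in 1 set. The list was also lower in miR29Nestin, where Dnmt3a is higher too (median −0.122, SE 0.070), so a lowering that goes with a higher level of Dnmt3a stays among the open explanations. Across the 28 genes the differences of the models hardly correlated (r = 0.106), and neither call held with an estimated correlation (adjusted p = 0.524 and 0.572). How the mice were handled before dissection, which sets the level of these genes, was not tested and stays open, as does age.

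Long genes were lower in both models. After removal of the GC and length trend the shift in miR29Nestin was −0.0381 (SE over libraries 0.0083; camera p = 0.0301, and p = 0.1 with an estimated correlation), which argues against that trend as the whole cause but leaves it open as a part, while in Dnmt3a-mi5 it was −0.0107 (SE 0.0038; p = 0.0479 and 0.0258), too near to the bound set for that trend for it to be told apart from other causes; neither value reached the bound set against the trend. A lower share of neurons in miR29Nestin would raise the markers of all other cell types alike only if their own proportions stayed the same. Among the astrocyte, oligodendrocyte, microglia and endothelial lists the medians ran from −0.02 for microglia to 0.13 for astrocytes, a range of 0.149 (SE 0.044). Without 184 genes of the neuron, synapse, channel and autism lists the shift was −0.0755. Excitatory neuron markers were lower (median −0.26), while interneuron markers did not pass (−0.07). As other cell types could change on their own, a lower share of neurons stays open as a cause of the shift. An effect of higher Dnmt3a on long genes may be part of it, but methylation was not analysed here, and the shift in miR29Nestin did not pass with an estimated correlation (p = 0.262, camera). Differences in RNA quality stay open as well: of the 2 lists kept as markers of it, oxidative phosphorylation genes were higher in miR29Nestin (median 0.13, camera adjusted p = 2.41e-06, and 0.390 with an estimated correlation), while ribosomal protein genes did not pass there (−0.03, 0.311).

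Lncpint and A330023F24Rik, which lie beside and over the 2 microRNA loci, were higher in miR29Nestin. Of the other 71 tested genes within 5 Mb of the loci 19 were called, 26.8% against 19.0% elsewhere (odds ratio 1.56, 95% CI 0.868 to 2.69, Fisher's exact p = 0.0971), so DNA of the 129 strain around the targeted alleles cannot be told apart from other causes. Over the genes called without it, miR29WT library 1 lay 0.151 of the way from the other miR29WT libraries to miR29Nestin, against 0.0408 and 0.0431 for libraries 2 and 3, so a targeted allele in that library, where A330023F24Rik had 4119 counts against 1143 and 1230, cannot be told apart from ordinary spread. At 15.3% (SE 0.830) of these genes it lay nearer to miR29Nestin, and it had 0.75 counts of Lncpint against 390 to 468, which argues against a miR29Nestin library under a wild-type label. An effect of the deletion itself on these 2 transcripts stays open as well, since reads over the deleted parts were not analysed here.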

How the results depend on the processing

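The fits with the removed effect as a term, with voom, with GC and length trends removed and with single libraries left out of the shared calls, the restriction to balanced splits and the replicate block in Dnmt3a-mi5 were tests chosen only after the results were seen.

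Dnmt3a kept its direction and its call under every alternative run. Without single libraries its difference ranged from 1.59 to 1.66 in miR29Nestin and from 0.67 to 0.73 in Dnmt3a-mi5, and voom gave 1.73 in miR29Nestin. The seed match and long gene shifts of miR29Nestin (0.0253 to 0.0520 and −0.1004 to −0.0529 without single libraries), the long gene shift of Dnmt3a-mi5 (−0.0315 to −0.0234) and the correlation between the models (0.242 to 0.295) kept their directions, and their calls without single libraries. With an estimated correlation the shifts of miR29Nestin did not pass (p = 0.0775 and 0.262, camera). No direction of a called result reversed.

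In miR29Nestin, 1399 (without miR29WT library 2) to 2314 genes were called without single libraries, with 1474 without miR29Nestin library 2 and 1435 without miR29WT library 3, and 1479 with an absolute difference of at least 0.26. With an estimated correlation 0 lists passed, against 7 at an unadjusted p under 0.05 and 13 by fry. The replicate block changed the calls of 8 of the genes and lists chosen by the rule, and over all genes 3037 were called, 2286 of them among the 2289 called without it. It was not run for the seed match and long gene shifts or the correlation.

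In Dnmt3a-mi5, 8 (without Dnmt3a-WT library 4) to 175 (without Dnmt3a-WT library 2) genes were called without single libraries. The count was 25 without a filter, 183 with array weights, 13 with the removed effect as a term, 6 with GC and length trends removed as well, 497 at an adjusted p under 0.1 and 20 with an absolute difference of at least 0.26. With an estimated correlation 0 lists passed camera (1 at an unadjusted p under 0.05, 0 by fry), and 0 with the stricter filter. The seed match shift ranged from −0.0165 (without Dnmt3a-mi5 library 1, where it passed) to −0.0110. Genes called in both comparisons numbered 153 at an adjusted p under 0.1, 47 with the stricter filter, 4 with the removed effect as a term and 2 (without Dnmt3a-WT library 4) to 58 (without Dnmt3a-WT library 2) without single libraries. Thresholds change counts by construction, and fits with fewer libraries or degrees of freedom tend to lose calls. The gains to 175 and 58 without Dnmt3a-WT library 2 went the other way. The cause of these gains and of the other changes was not tested.

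Of 165 genes and lists chosen by the rule in miR29Nestin 127 were called, and 104 of these kept their call without each library. Of 167 in Dnmt3a-mi5 39 were called and 11 kept it; the removed effect as a term ended 24 calls and the missing filter 21. The 18 splits of the Dnmt3a libraries balanced over the 2 sets are too few for a share under 0.05. The real values there were 85 genes, 4 lists and shifts of −0.0131 and −0.0273, and the highest others 0, 8, 0.0123 and 0.0254, with 1, 12, 1 and 1 splits as large. For the 23 shared calls 1 of 100 pairs of splits was as large and the highest other was 0, but as other splits of the Dnmt3a libraries called 0 genes this could not decide. The 10 splits of the miR29 libraries are too few for a share under 0.05. The real values there were 2289 genes, 14 lists and shifts of 0.0419 and −0.0793, and the highest others 4, 12, 0.0346 and 0.0701. The 3 other splits that part all 3 pairs of equal replicate number called 0 genes by limma, and those that part 1 pair at most 4.

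In Dnmt3a-mi5 the column headers repeat the numbers 1 and 2 in each of the 2 sets. Libraries of the same set and number correlated at −0.147, −0.265, −0.555 and −0.525 in their deviations from the group means, with none matching its own number best. The equal set means tie the deviations of a set's wild-type libraries to the opposite of those of its mutant libraries, which lowers these correlations by construction. The test could therefore not decide whether these numbers pair the samples. With them as a replicate block 2 genes were called, both also called without it, and 4 lists passed. With a block in both models 1 gene was shared. Sex may coincide with the removed effect there. The endothelial list gave no value with the stricter filter. Read depth is unknown for Dnmt3a-mi5, so what it limits cannot be stated; in the miR29 table genes under about 48.0 normalised counts were not tested.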
